A study of Medicago sativa with 6 samples.

How the data were processed

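RNA was sequenced from 6 tissues of the alfalfa (Medicago sativa) genotype RegenSY27x: flower, leaf, nodules, roots, seedpod and stem. Per the labels' protocols, the plants grew at 22 °C by day and 18 °C by night with 16 hours of light, and 3 replicates of each tissue were harvested. RNA was extracted with a column kit and pooled, and 1 barcoded library per tissue was sequenced in multiplex with paired-end reads. The growth protocol gives the tissue age as 8 weeks, whereas the stage label carries the number 20 with an unclear unit, and the age was not settled. The sample title of the flower library names flower buds.

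The authors deposited 1 table of raw counts per gene, with the gene identifier, the position of every exon, the strand, the summed exon length and 1 count column for each of the 6 libraries, per the file headers. Trimmomatic, FastQC, featureCounts and edgeR are named, without versions, per the submitters' processing notes. The exon-length sums, a quantity other than a count, are also the authors' own values, per the file headers. The aligner, the genome build, the strand setting and the treatment of reads that match several places are not given in the sources used here. The table holds 164633 genes. They lie on 32 chromosome sequences (8 chromosomes with 4 haplotypes each), on numbered scaffolds (5738 genes), and on 1 separate sequence for a gene named MS.genePho2-1d. Of the exon-length sums, 95.6% were multiples of 3, so they are called coding lengths below. No row was blank or a total. Because alfalfa is tetraploid and the annotation lists haplotypes separately, near-identical copies compete for reads, and how the authors' counting split them is uncertain for any single gene. Reads of overlapping or antisense genes cannot be told apart here either.

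The table pairs its identifiers with no gene names, apart from MS.genePho2-1d. None of its identifiers matched a table of 63463 genes of another alfalfa assembly (Bolivia_mono; 0 matches). Of 13 gene lists fixed before the data were examined, only the PHO2 list could therefore be resolved, by the name of that row. The lists for phosphate transport and signalling, photosynthesis, nodulation, flower identity and pollen, seed storage, cell wall and lignin, root uptake, flavonoids, defence, ribosomal proteins, housekeeping and organelle or rhizobial transcripts have no value here. Markers of other tissues could not be used to look for carry-over of tissue.

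Each library was scaled by its total times the factor from edgeR 4.0.16 (trimmed mean of M-values, TMM) over all 6 libraries, in R 4.3.3. Values are counts per 1000000 of the scaled library total, written TMM CPM. With 1 pooled library per tissue there is no replicate check of any difference, and no p-value is given. Genes were called by rules of size fixed before the data were examined. A gene was enriched in a tissue at 10 or more TMM CPM there and at least 10 times the highest of the other 5 libraries. It was depleted when its level was at most 0.1 times the lowest of the other 5, all at 10 or more. For pairs of tissues and for underground against aerial tissues the rule was 10 TMM CPM and 4 times. Where the low side had 0 counts, the ratio was taken against 3 counts per library, as a lower bound. Intervals are 95% exact Poisson intervals for levels and exact conditional binomial (Clopper-Pearson) intervals for ratios and shares. They cover counting error only, since reads without molecular identifiers are not independent molecules and biological variation was averaged in the pools.

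The named genes were fixed by rule: at most 2 identifiers higher and 2 lower per comparison, those with the highest TMM CPM on the high side (for depletion, in the lowest of the other libraries), because the files do not pair identifiers with names. Genes picked out beside these were chosen after their values were seen and are given by position. Similarity of tissues was measured across 59313 genes at 1 TMM CPM or more in any library, as Pearson's r of log2(TMM CPM + 1). The coding length and exon number of each enriched set were set against 10000 random lists of the same size, drawn from the 28247 genes at 10 TMM CPM or more in any library and matched on mean expression in 20 bins. These percentiles describe these libraries and are no test of the tissues. The lists drew genes independently, whereas copies on different haplotypes can enter an enriched set together, so the percentiles can be too extreme. The comparisons of coding length, exon number and position, the limits of 300 and 450 nucleotides for short genes, and the sets shared by a pair of tissues were chosen after the data had been seen. Genes with the same chromosome number and the same chain of exon lengths, with at least 3 exons, were treated as same-structure copies, a grouping added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

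Recurrence between libraries was measured, after the data had been seen, on genes nearly confined to 1 library (500 or more and under 5000 counts there, at most 1% of that in each other), as the pooled counts in another library in percent of those in the first. The named genes set against these shares had more than 5000 counts in the high library, so they lie above this range.

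Calls were tested on simulated data first: Poisson counts for the 164633 genes at the real library totals, with 100 genes raised 20-fold and 100 raised 5-fold in nodules. The enrichment rule called 100 of the 20-fold genes, 0 of the 5-fold genes and 0 others. The rule for nodules against roots called all 100 of each kind and 0 others. Apart from the raised genes, every simulated library had the same expected profile, so these outcomes were largely fixed by the rules. They check the calling steps and do not measure false calls between real tissues. Alternatives were DESeq2 1.42.0 size factors, plain library totals, totals without the 20 most abundant genes of any library, other expression minimums, other fold thresholds, the lower end of the interval in place of the ratio, other pseudocounts and filters, sums over same-structure copies, and leaving out the leaf library. Library totals ranged from 8568581 to 9883512 counts. After scaling, 1 count was worth from 0.0960 TMM CPM in stem to 0.139 in leaf, and the upper limit that a count of 0 allows (3 counts, a one-sided 95% limit, unlike the intervals with both ends of levels) ranged from 0.288 TMM CPM in stem to 0.418 in leaf.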

Results

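Gene expression was measured in 6 tissues of alfalfa, a tetraploid forage legume, in the genotype RegenSY27x. Each of flower, leaf, nodules (the root organs that house nitrogen-fixing bacteria), roots, seedpod and stem was represented by 1 library of pooled RNA, so no tissue had replicates. The total counts were 9018902 in flower, 8846524 in leaf, 9883512 in nodules, 8568581 in roots, 8735091 in seedpod and 8829264 in stem. Of 164633 annotated genes, 68630 (41.7%) had no count in any library, 58887 had at least 10 counts in some library and 24466 had at least 10 in every library. All intervals given are 95% intervals of counting error.

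The series is named for pho2 mutants of alfalfa that over-accumulate phosphate, and the first question was where PHO2 was expressed. PHO2 is a ubiquitin-conjugating enzyme that limits phosphate uptake and its transfer to the shoot. The gene MS.genePho2-1d lies on a sequence of its own, assigned by its name to chromosome 2.4, from position 1 to 3932, with 7 exons and a coding length of 2739 nucleotides. Its level was highest in roots, at 107 TMM CPM (interval 101 to 114, 1012 counts), followed by leaf at 78.6 (72.2 to 85.3). Nodules and seedpod lay lower, at 37.3 (33.2 to 41.7) and 36.4 (32.6 to 40.6). Flower at 14.1 (11.9 to 16.6) and stem at 8.83 (7.12 to 10.8) were lowest. Roots thus stood 12.2-fold above stem (interval 9.81 to 15.2), 7.61-fold above flower (6.38 to 9.14), 2.88-fold above nodules (2.53 to 3.28) and 1.37-fold above leaf (1.23 to 1.52). Seedpod and nodules differed by less than counting error, with a ratio of 0.977 (0.834 to 1.15), or 1.21 with library totals. The ratio of roots to leaf was 1.28 with DESeq2 size factors and 1.85 with library totals. On the log2 scale the root level was 1.98 above the mean of the other 5 tissues, which placed the gene at the 94th percentile of 1000 genes of like mean expression. The leaf value, 1.45 above the mean of the others, was at percentile 77.1, and the stem value of -2.25 was at percentile 4.2.

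The annotation holds 3 further genes on chromosome 2 whose exons 2 to 7 have the same lengths as those of MS.genePho2-1d. They were found from the exon coordinates after the values had been seen, and their sequences were not compared. The copy on chromosome 2.1 (71269986 to 71273927, 2751 nucleotides of coding length) reached 103 TMM CPM in roots (96.6 to 110.) and 92.9 in leaf (86.0 to 100.2). The copy on chromosome 2.2 (69045836 to 69049771, 2751 nucleotides) reached 115 in roots (109 to 122) and 50.4 in leaf (45.4 to 55.9). The copy on chromosome 2.3 (25049449 to 25053382, 2739 nucleotides) was lower, at 33.9 in roots (30.3 to 37.9) and 44.2 in leaf (39.4 to 49.3). In the copy on chromosome 2.1, roots and leaf were close, at a ratio of 1.11 (1.004 to 1.23). For the copy on chromosome 2.3 the root-to-leaf ratio was 0.769 (0.656 to 0.901) with TMM scaling but 1.04 with library totals, so the order of roots and leaf for this copy depended on the scaling. Stem had the lowest value in each of the 4 copies, from 3.94 TMM CPM in the copy on chromosome 2.3 to 11.2 in the copy on chromosome 2.1. Flower was not distinguishable from stem by counting error in the copies on chromosome 2.1 (ratio 1.25, interval 0.969 to 1.61) and 2.2 (1.18, 0.902 to 1.54). Summed over the 4 copies, roots stood at 359.8 TMM CPM (348 to 372), leaf at 266 (254 to 278), nodules at 105 (98.5 to 113), seedpod at 105 (98.3 to 112), flower at 46.4 (42.3 to 50.8) and stem at 34.4 (30.9 to 38.1).

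Another 4 genes, 1 on each haplotype of chromosome 4, have 7 exons and share the lengths of exons 4 to 7 with MS.genePho2-1d, a resemblance in structure only, also found after the values had been seen. Their summed level was 87.2 TMM CPM in roots (81.3 to 93.4), 61.0 in nodules (55.8 to 66.6), 55.7 in seedpod (50.9 to 60.8) and 49.6 in stem (45.4 to 54.1). Flower had 11.4 (9.43 to 13.7). In leaf the 4 genes had 7 counts together, or 0.975 TMM CPM (0.392 to 2.01), and the stem level was 50.9-fold higher than that of leaf (24.5 to 127). The chromosome 2 copies went the other way between these tissues, with leaf 7.74-fold above stem (6.91 to 8.69).

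**Figure D1:**
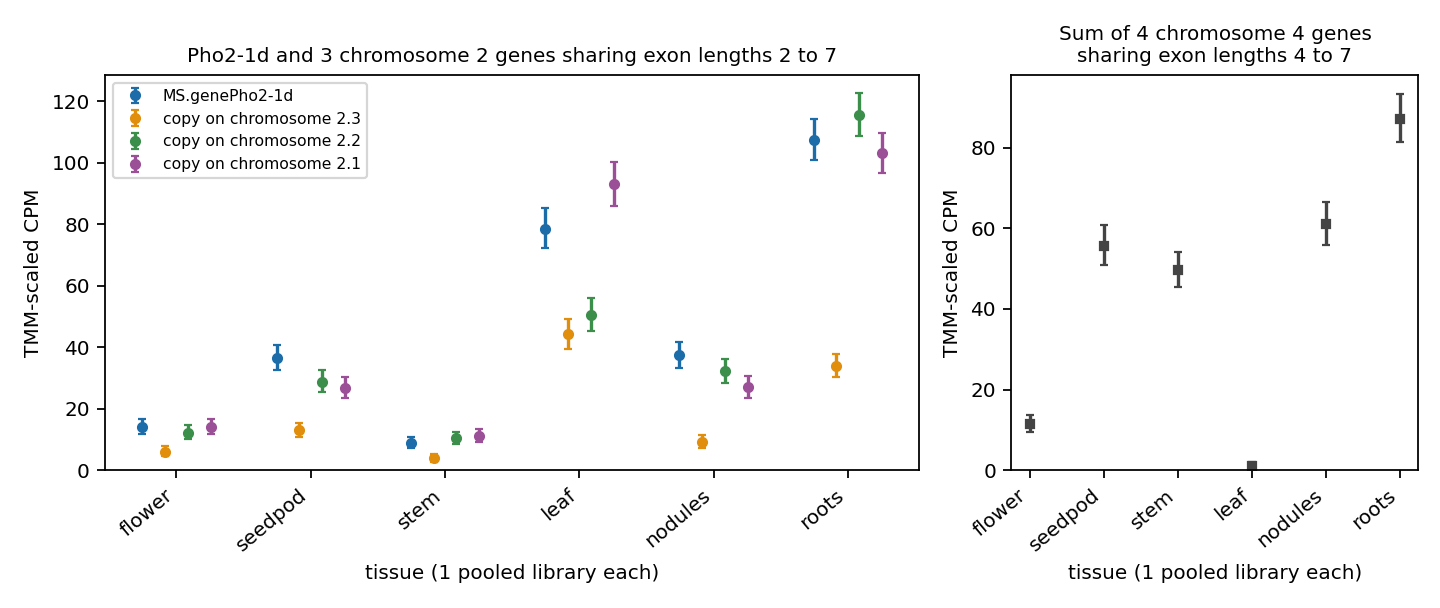
Level of MS.genePho2-1d and the 3 chromosome 2 genes that share the lengths of its exons 2 to 7 (left, TMM CPM) and of the 4 genes on chromosome 4 that share the lengths of exons 4 to 7 (right, summed) in each tissue. Points are single pooled libraries and bars are 95% Poisson intervals; the left group is high in roots and leaf and low in stem and flower, whereas the right group is near 0 in leaf, at 0.975.

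The libraries differed in how many genes were detected, mainly through leaf, and in how concentrated the counts were. At 10 or more counts, 42712 genes were detected in stem, 42357 in roots, 42281 in flower, 41327 in seedpod and 40687 in nodules, against 33457 in leaf. Thinned to 8568581 counts per library, the order of leaf did not change: 33189 genes were detected in leaf and 39087 to 42416 in the others. The 10 most abundant genes took 8.19% of the counts in nodules (8.17 to 8.20), 5.93% in flower (5.91 to 5.94), 5.61% in leaf (5.60 to 5.63), 4.11% in seedpod (4.10 to 4.12), 3.27% in roots (3.26 to 3.28) and 2.13% in stem (2.12 to 2.14). This order depended on the measure: the 100 most abundant genes took 19.7% in leaf and 18.7% in nodules. MS.gene010103 alone made up 2.88% of the nodule library.

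Flower, seedpod and stem resembled each other most. Across genes, which are not independent replicates, r was 0.866 for flower and stem, 0.866 for seedpod and stem, and 0.854 for flower and seedpod. Nodules and roots followed at 0.796. The highest r of leaf was 0.677, with stem, whereas each of the other tissues reached at least 0.796 with some tissue. The mean r with the other 5 was lowest for nodules, at 0.621, and next for leaf, at 0.637. With a pseudocount of 5 or over all genes with any count, leaf was lowest instead. Of the 15 pairs, the lowest values were those of nodules with flower (0.553) and with seedpod (0.555). Spearman's rho ranged from 0.514 for flower and nodules to 0.852 for flower and stem.

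**Figure D2:**
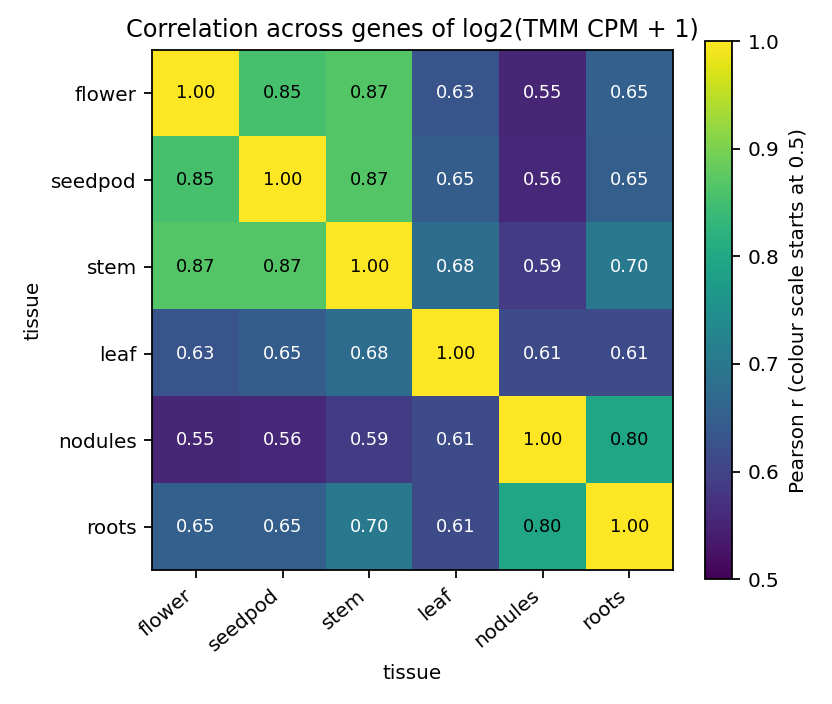
Pearson correlation across 59313 genes of log2(TMM CPM + 1) for each pair of tissues, 1 pooled library per tissue. The colour scale starts at 0.5; flower, seedpod and stem form a block at 0.854 to 0.866, nodules and roots pair at 0.796, and leaf stays at or below 0.677 with every other tissue.

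The next comparisons asked which genes marked each tissue against the other 5. The TMM scaling raised leaf values by 0.30 and nodule values by 0.27 on the log2 scale relative to library totals, and changed stem by -0.24, flower by -0.16, roots by -0.14 and seedpod by -0.04. Tallies of the next highest tissue of the enriched sets below used this scaling only. Nodules had the most enriched genes, 920, then leaf with 503, seedpod with 333, roots with 268, flower with 171 and stem with 39. Seedpod and roots changed places with the scaling, at 333 and 349 with library totals and at 346 and 351 with totals without the most abundant genes. Depletion was rare outside leaf: 248 genes were depleted in leaf and between 3 and 13 in each other tissue. The depletion counts of the other tissues rested in part on the leaf library, since without it they were between 9 and 50. Held to the lower end of the interval, 86 depleted genes were left in leaf, 5 in nodules, 2 each in flower and seedpod, and 0 in roots and stem.

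**Figure D3:**
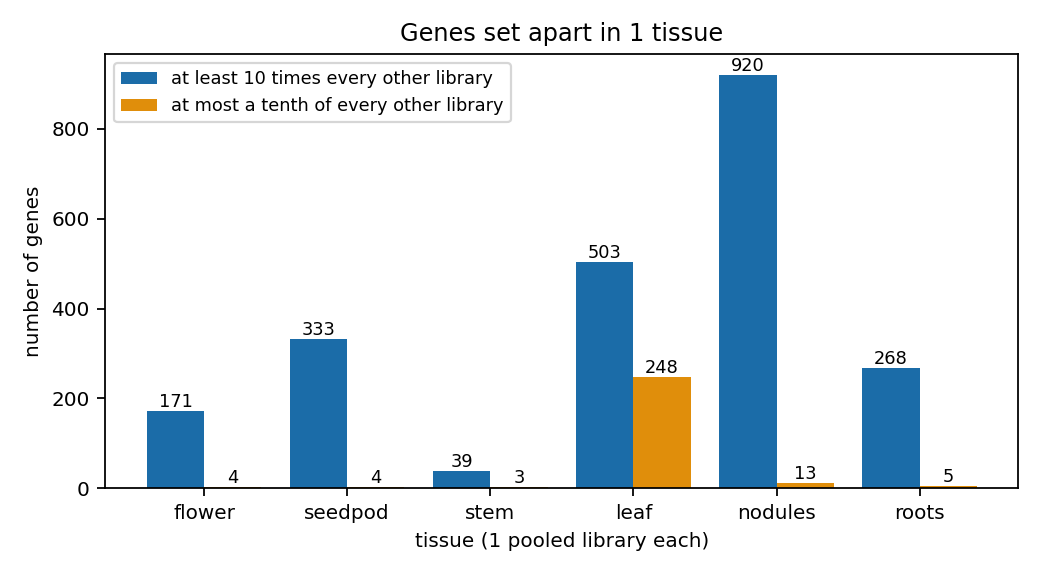
Number of genes at 10 or more TMM CPM and at least 10 times every other library (blue), and number at most 0.1 times every other library (orange), per tissue, 1 pooled library each. Nodules have the most enriched genes (920) and leaf the most depleted genes (248).

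In nodules the 920 enriched genes carried 17.8% of all counts, and their median ratio to the next tissue was 36.5. Roots were the next highest tissue for 482 of them, and in 71 the other 5 libraries had no count. Enriched genes were short in all 6 tissues: against a median coding length of 1215 nucleotides over all expressed genes, the medians were 753 in stem, 957 in flower, 979.5 in roots, 997.5 in nodules, 1014 in leaf and 1050 in seedpod, at percentiles of 0 to 0.58. Of the nodule set, 16.1% were shorter than 450 nucleotides against 8.62%, and 23.4% had a single exon against 15.9%. Against the 10000 matched random lists both shares stood at percentile 100. Single-exon shares were also high in roots (28.7%), flower (25.1%) and seedpod (23.7%). Below 300 nucleotides the share was 4.57% against 2.55% (percentile 99.94). The most abundant enriched gene was MS.gene010103 on chromosome 5.2 (56059595 to 56062028, 4 exons, 444 nucleotides), at 34773.4 TMM CPM in nodules (34645.7 to 34901.4). Its next highest tissue was leaf at 74.0, a ratio of 470.2 (432 to 513), but roots with library totals. The leaf counts were 0.187% of the nodule counts, where genes nearly confined to nodules recurred in leaf at 0.0954%, so the exact fold is not firm. MS.gene040567 on chromosome 2.3 (26805594 to 26807124, 4 exons, 630 nucleotides) had 11783.9 TMM CPM in nodules and 147 in roots, a ratio of 80.1 (75.9 to 84.5). Among the 13 depleted genes, MS.gene36789 (chromosome 8.2, 79283560 to 79284991) had 10.8 TMM CPM in nodules and at least 137 elsewhere. MS.gene30782 (chromosome 3.1, 59642949 to 59645898) had 4.16 in nodules and at least 53.7 elsewhere. Its ratio of 12.9 (9.12 to 18.9) did not meet the rule by the lower end of its interval.

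The 503 leaf-enriched genes carried 13.5% of the leaf counts, with a median ratio of 20.3. For 165 of them nodules were the next highest tissue, for 122 seedpod, for 86 stem, for 64 flower and for 60 roots. Relative to library totals, the TMM scaling raised nodule values and lowered those of seedpod, stem, flower and roots, so this order can depend on the scaling. MS.gene062068 on chromosome 2.3 (45194515 to 45196161, 5 exons, 558 nucleotides) had 12549.2 TMM CPM in leaf (12467.4 to 12631.4). In nodules it had 449 and in the remaining tissues 7.25 to 15.7, so that leaf was 27.9-fold above nodules (27.0 to 28.9). MS.gene85296 on chromosome 2.4 (45328462 to 45329256, 3 exons, 351 nucleotides) had 10177.1 TMM CPM in leaf and 180 in nodules, a ratio of 56.5 (53.6 to 59.5). Of the 248 depleted genes, MS.gene031329 (chromosome 2.1, 19139262 to 19140749) had 16.7 TMM CPM in leaf, 319 in flower and 1729 in roots. MS.gene066864 (scaffold 16761, 20478 to 22775) had 7.10 in leaf, 237 in nodules and 1965 in flower.

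In seedpod 333 genes were enriched, and these had the largest median ratio of the 6 sets, 64.1. They carried 2.67% of the seedpod counts, and in 47 the other libraries had no count. MS.gene064782 on chromosome 3.4 (98111335 to 98115970, 9 exons, 2040 nucleotides) had 1925.9 TMM CPM in seedpod (1897.3 to 1954.9), against 19.4 in leaf and 3.50 or less elsewhere. The ratio to leaf was 99.5 (84.2 to 118). MS.gene061670 on chromosome 1.3 (18829591 to 18831802, 3 exons, 1062 nucleotides) had 933 in seedpod and at most 1.96 elsewhere, a ratio of 477 (294 to 835). The 16 nodule counts behind that ratio were 0.191% of the seedpod counts, close to the 0.151% at which genes nearly confined to seedpod recurred in nodules, so neither the exact fold nor the next highest tissue is firm. Only 4 genes were depleted in seedpod. MS.gene77482 (chromosome 3.2, 72141610 to 72143137) had 2 counts there and 673 TMM CPM in leaf. The lowest of the other libraries, stem, was 78.0-fold above seedpod (21.3 to 648.8), and with 2 counts on the low side this fold is not firm. MS.gene026849 (chromosome 2.4, 20957287 to 20958597) had 1.11 in seedpod and at least 14.998 elsewhere. Its ratio of 13.5 (7.12 to 28.6) did not meet the rule by the lower end of its interval.

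The 268 root-enriched genes had nodules as their next highest tissue in 222 cases, and their median ratio was 19.4. They carried 2.10% of the root counts. Single-exon genes made up 28.7% of the set against 15.9% of all expressed genes (percentile 100). MS.gene060989 on chromosome 2.3 (23789559 to 23792189, 1 exon, 2631 nucleotides) had 1479 TMM CPM in roots (1454.6 to 1503.8), 136 in nodules and at most 2.56 in the aerial tissues. MS.gene048252, also on chromosome 2.3 (62552957 to 62553340, 1 exon, 384 nucleotides), had 965 in roots, 85.2 in nodules and at most 1.81 in the aerial tissues. Of the 5 depleted genes, MS.gene39520 (chromosome 4.2, 22922461 to 22926000) had 1.17 TMM CPM in roots and 12.2 in nodules. That ratio of 10.5 had an interval of 5.61 to 21.7. MS.gene61944 (chromosome 5.2, 57366869 to 57369524) had 0.530 in roots and at least 11.7 elsewhere, a ratio of 22.1 (9.09 to 69.7). None of the 5 met the rule by the lower end of its interval.

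In flower 171 genes were enriched, with a median ratio of 40.2 and 1.48% of the counts. Seedpod was the next highest tissue for 66 of them. MS.gene84312 on chromosome 2.2 (12014419 to 12014766, 1 exon, 348 nucleotides) had 2072.9 TMM CPM in flower (2044.8 to 2101.2), 49.9 in seedpod and 28.8 in stem. MS.gene025288 on the same chromosome (44645641 to 44654788, 14 exons, 1650 nucleotides) had 743 in flower and at most 1.25 in any other tissue, a ratio of 593 (312 to 1297). Its 9 leaf counts were 0.120% of the flower counts, below the 0.167% at which genes nearly confined to flower recurred in leaf, so this ratio is not firm. Of the 4 depleted genes, MS.gene059052 (chromosome 2.4, 55913023 to 55914026) had 0.795 TMM CPM in flower and 279 in roots. MS.gene000683 (chromosome 7.3, 82187366 to 82188403) had 1.09 in flower and at least 23.3 elsewhere.

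Stem had the fewest genes of its own, 39, with 0.304% of the counts. Its set was the shortest, with a median coding length of 753 nucleotides (percentile 0.07) and 33.3% of members under 450 nucleotides (percentile 99.99), though the 5.13% under 300 nucleotides did not stand apart (percentile 68.5). The most abundant pair had the same length and exon number: MS.gene97976 on chromosome 8.4 (33102475 to 33103707, 2 exons, 363 nucleotides) at 661 TMM CPM (645 to 677), and MS.gene008799 on chromosome 8.1 (34523027 to 34524203, 2 exons, 363 nucleotides) at 299 (288 to 309). They stood 73.2-fold (58.8 to 92.3) and 78.2-fold (56.4 to 112) above the next tissue. Of the 3 depleted genes, MS.gene24109 (chromosome 1.2, 305757 to 308153) had 3.26 TMM CPM in stem and at least 36.3 elsewhere, and MS.gene065569 (chromosome 2.2, 22176752 to 22178438) had 2.59 and at least 36.1. None of the 3 depleted genes met the rule by the lower end of its interval.

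Nodules and roots, which form part of the same organ system, were compared directly. At 4-fold or more, 2763 genes were higher in nodules and 1807 in roots. The former include all 920 nodule-enriched genes (33.3%) by construction, since the enrichment rule is the stricter. MS.gene010103 was 612-fold higher in nodules (562 to 667), and MS.gene040567 80.1-fold. The root counts of MS.gene010103 were 0.188% of its nodule counts. Genes nearly confined to nodules recurred in roots at 0.220%. The 25 such genes with 5000 or more nodule counts had a median of 0.136% in roots. The share of MS.gene010103 lies between these values, so its fold is not firm. On the root side, MS.gene90104 on chromosome 1.4 (88487619 to 88492417, 3 exons, 4026 nucleotides), the most abundant root gene at 8195.2 TMM CPM, was 4.17-fold higher in roots (4.10 to 4.24). MS.gene80665 on chromosome 5.4 (64726580 to 64730014, 4 exons, 870 nucleotides) had 2018.8 in roots and 336 in nodules. The balance between the sides rested on the scaling: 60.5% of the genes were higher in nodules with TMM, 61.2% with DESeq2 size factors, 44.7% with library totals and 48.5% with totals without the most abundant genes.

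Leaf and stem differed in more genes than the other pairs compared, with 3939 higher in leaf and 4457 higher in stem. The leaf side held 49.2% of the leaf counts. MS.gene062068 was 1221.7-fold (1010.9 to 1490.9) and MS.gene85296 1191.1-fold (967.8 to 1483.4) higher in leaf. Their stem counts, 107 and 89, were 0.119% and 0.122% of the leaf counts. Genes nearly confined to leaf recurred in stem at 0.235% of their leaf counts, so neither fold is firm. On the stem side, MS.gene76713 on chromosome 4.1 (71166483 to 71167184, 2 exons, 351 nucleotides) had 1891.1 TMM CPM in stem and 8.77 in leaf, a ratio of 216 (168 to 281). Its leaf counts were 0.320% of the stem counts. Only 1 gene was nearly confined to stem, and it recurred at 0.345% in leaf, 0.431% in flower and 0% in nodules. A single gene gives no firm level to compare with, so recurrence could not be judged and this fold is not firm either. MS.gene55076 on chromosome 7.2 (25241906 to 25248705, 11 exons, 2391 nucleotides) was 8.29-fold higher in stem (7.87 to 8.73). The leaf side made up 46.9% of these genes with TMM and 51.8% with DESeq2 size factors, but 29.5% with library totals and 31.6% with totals without the most abundant genes.

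Between seedpod and flower, the organ from which pods develop, 1547 genes were higher in seedpod and 939 in flower. MS.gene070146 on chromosome 2.4 (45986692 to 45991298, 13 exons, 2415 nucleotides) was 5.94-fold higher in seedpod (5.76 to 6.13). MS.gene87999 on chromosome 4.3 (70185592 to 70186287, 1 exon, 696 nucleotides) was 24.6-fold higher (23.0 to 26.3) and had its highest level in roots, at 4043.1 TMM CPM. On the flower side, MS.gene07845 on chromosome 8.3 (71819912 to 71823665, 9 exons, 2598 nucleotides) was 6.71-fold higher (6.52 to 6.91), and MS.gene84312 was 41.5-fold higher (37.8 to 45.7). Seedpod held 62.2% of these genes with TMM and 55.0% to 61.9% with the other scalings.

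Roots and nodules together were set against the 4 aerial tissues. In 875 genes both underground libraries stood at least 4-fold above every aerial one, and in 372 genes every aerial library stood at least 4-fold above both underground ones. MS.gene37357 on chromosome 8.4 (74755577 to 74760274, 9 exons, 2607 nucleotides) had 3823 TMM CPM in roots and 1998 in nodules, against at most 39.9 in aerial tissues. MS.gene07844 on chromosome 8.3 (71825073 to 71830329, 9 exons, 2595 nucleotides) had 1185.4 in nodules, 856 in roots and at most 167 in aerial tissues. On the aerial side were 2 single-exon genes of 801 nucleotides on different haplotypes of chromosome 4. MS.gene35137 (chromosome 4.4, 19515116 to 19515916) ranged from 1480.9 to 3202.7 TMM CPM in aerial tissues and reached 29.7 in roots. MS.gene023132 (chromosome 4.3, 19109525 to 19110325) ranged from 1294.9 to 2347.7 and reached 24.2 in nodules. The underground share of these genes was 70.2% with TMM and 70.0% to 70.5% with the other scalings. Only 2 libraries had to be high on the underground side, but 4 on the aerial side. The split is therefore set in part by the rule and does not compare the 2 sides evenly. The aerial count depended on the leaf library, rising to 888 without it, and the underground count was not recomputed without leaf.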

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

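No paired analysis was possible because each tissue had 1 pooled library; for the same reason no replicate could be left out. Settings for the marker lists were not run for want of gene names, the mean over members and the 1 CPM member filter were not run because the PHO2 list had 1 member, leaving out runs was not run because each library had 1 column, and sums over same-structure copies replaced those over allele groups. These sums, the fits without the leaf library and the PHO2 sum over the copies sharing exons 2 to 7 were chosen after seeing the data. Orders below are flower, leaf, nodules, roots, seedpod, stem. Enriched genes numbered 171, 503, 920, 268, 333 and 39 as reported, and depleted genes 4, 248, 13, 5, 4 and 3. DESeq2 size factors moved no count past 1.5 times. For the other settings, counts of called genes are listed where they moved past 1.5 times, unless marked as within it. Library totals gave 2551 genes higher in leaf than stem (3939 as reported) and 2, 20, 1 and 0 depleted in flower, nodules, roots and stem. Totals without the 20 most abundant genes gave 22 and 2 depleted in nodules and roots. A minimum of 1 TMM CPM gave 384, 1457, 603, 689 and 107 enriched genes outside leaf, 50, 882, 90, 63, 29 and 19 depleted genes, 5664 and 5221 for nodules against roots, 6872 and 11339 for leaf against stem, 4428 and 3226 for seedpod against flower, and 2416 and 1035 for underground against aerial. A minimum of 50 TMM CPM gave 52, 302, 431, 76, 100 and 11 enriched, 0, 41, 2, 0, 0 and 0 depleted, 1154 and 432, 1910 and 1211, 527 and 279, and 238 and 78 in the same order of comparisons. With fold thresholds of 5 and 2 the values were 316, 1210, 1473, 519 and 112 enriched genes without seedpod, 17, 603, 44, 11, 7 and 9 depleted, 4830 and 3671, 7391 in leaf, 3156 and 2288, and 1319 and 599. With 20 and 8 they were 256, 128 and 20 enriched in leaf, roots and stem, 2, 86, 5, 1, 2 and 0 depleted, 1701 and 909, 2069 and 2959, 943 and 495, and 241 on the aerial side. Requiring the lower end of the interval to pass gave 144 and 21 enriched in roots and stem, and 2, 86, 5, 0, 2 and 0 depleted. Summing same-structure copies gave 2 depleted in seedpod. Within 1.5 times, it lowered the enriched counts to 161, 411, 786, 224, 299 and 38. The reported counts can include separate copies of such sets, but calls merged and calls lost by summing were not counted apart. Without the leaf library 12, 50, 17, 9 and 16 genes were depleted in flower, nodules, roots, seedpod and stem, and 888 were higher in aerial tissues. The underground side was not run without it. A minimum of 1 count detected 70553, 60081, 68795, 69406, 70755 and 68324 genes, leaf again the fewest. Outside leaf the order changed: stem, the highest at 10 counts, was the lowest, and seedpod was the highest. The 100 most abundant genes took 16.0, 19.7, 18.7, 12.1, 14.994 and 10.3% of counts, and after division by coding length the top 10 took 5.06, 11.0, 13.8, 2.96, 3.39 and 3.39%, which changed the order: leaf stood above nodules by the 100 most abundant genes, and by length leaf stood above flower and stem above roots, with stem and seedpod nearly equal. The correlation of flower and nodules was 0.700 over all genes with any count and 0.281 over genes at 10 CPM, and that of nodules and roots was 0.680 over the latter. The mean r was lowest for leaf instead of nodules with a pseudocount of 5 or over all genes with any count. The lowest pair became nodules and seedpod with a pseudocount of 0.1 or the 10 CPM filter, and the highest became seedpod and stem with a pseudocount of 5. For MS.genePho2-1d the log2 difference of roots to the mean of the other 5 was 1.98 as reported, 2.15 with library totals, 1.77 with a pseudocount of 5 and 0.45 against leaf, the highest other tissue. For the 40 values of named genes, 21 of 80 alternatives (DESeq2 size factors and library totals) moved the ratio beyond its counting interval and none turned its direction. Stricter or looser rules let fewer or more genes pass by construction; for the changes with library totals, summed copies and similarity the cause was not tested. Depth limits the depletion calls, because their low side rests on few counts, and on none in 4 genes of leaf and 1 of nodules.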

Other observations

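The tests on sequencing depth and on carry-over between libraries, the sets shared by 2 tissues, the neighbours, the counts per chromosome and the lookup of copies led by roots were chosen after the values had been seen. The tests on abundant genes, on coding length in leaf and on copies at 80% or more of all counts were set before their results, the last after the counts of single copies had been seen.

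Genes shared by 2 tissues to the exclusion of the others were counted beside the correlations. Requiring both tissues to be at 10 TMM CPM or more and at least 4-fold above the other 4, 875 genes were shared by nodules and roots, 262 by leaf and nodules, 132 by flower and seedpod and 120 by seedpod and stem. Leaf and stem shared 14 genes, and leaf and roots 20. Because the other 4 tissues must be low, leaf and stem genes also high in flower or seedpod are not counted. The rule does not ask for like levels in the 2 tissues. These counts therefore do not rank likeness: r was 0.677 for leaf and stem and 0.614 for leaf and nodules. The leaf and nodule count was 283 with DESeq2 size factors, 170 with library totals and 184 with totals without the most abundant genes. The pair of leaf genes with the highest levels, MS.gene062068 and MS.gene85296, belonged to this kind of profile, with nodules next at 449 and 180 TMM CPM and the other tissues at 15.7 or less.

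Genes enriched in the same tissue lay side by side more than in random lists, though most did not. Among the 920 nodule-enriched genes, 99 were followed directly on the chromosome by another, against a median of 8 and a highest value of 20 in 10000 matched random lists. The longest run was 7 adjacent genes on chromosome 6.1 (60866617 to 61050510). Such neighbours numbered 18 in each of the leaf, root and seedpod sets, where the random lists reached at most 11, 6 and 6. In flower there were 4 and in stem 2, equal to the highest random values of 4 and 2 (percentiles 99.99 and 99.96). Nodule-enriched genes were also more frequent on chromosomes 5 and 6 than in random lists: 147 against a median of 108 (percentile 99.98), and 96 against 65 (percentile 99.99). They were fewer on chromosome 1, 109 against 135 (percentile 0.42). Root-enriched genes were fewer on chromosome 3, 15 against 34 (percentile 0). Of the 39 stem-enriched genes, 13 lay on chromosome 8, against 5 (percentile 99.93). These values come from a family of 6 tissues by 8 chromosomes. The random lists drew genes independently, but haplotype copies and adjacent genes can be enriched together. A single locus can thus count several times, and the percentiles of this paragraph can be too extreme.

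Between positions 71819912 and 71981593 of chromosome 8.3, 5 genes with 9 exons each and coding lengths of 2592 to 2610 nucleotides differed by tissue. MS.gene07845 had 3933.1 TMM CPM in flower and 586 in seedpod. The next in order, MS.gene07844, had 1185.4 in nodules, 856 in roots, 167 in seedpod and 98.0 in flower. The gene at 71887649 to 71891752 was the most abundant of the flower library, with 12311.1 in flower, 10387.5 in seedpod and at most 89.7 elsewhere. The gene at 71895679 to 71900503 had 8327.5 in flower and 2329.3 in seedpod. The gene at 71977276 to 71981593 had 7.33 in nodules and at most 0.106 elsewhere.

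The leaf library stood apart from the other 5, with the fewest detected genes, 248 depleted genes and no r above 0.677. Sequencing depth and crowding out by a few genes are argued against: with all libraries thinned to one total the leaf library still had 15.1% fewer detected genes than the lowest of the others, and without the 100 most abundant genes of each library, 14.4% fewer genes reached 1 CPM in leaf than in the lowest other library. Loss of long transcripts would lower long genes in leaf, but the median log2 ratio of leaf to the other tissues was -0.60 in the shortest 20% of coding lengths relative to the longest 20%, so long genes were relatively higher. The bound set beforehand, a size under 0.5, was wrong because it ignored the sign, and this was seen only with the value (the other 5 libraries ranged from -0.27 to 0.35). A difference between the tissues may be the reason, as the design allows, but other properties of this 1 pool, including the age and state of the leaves, were not tested.

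Abundant transcripts of 1 tissue recurred at a low level in the other libraries, which were sequenced in multiplex. In 36 genes with 5000 or more counts in a library and at most 1% of that in each other, the lowest of the other libraries was above 0.01% of the source in 100% of genes, with a lowest value of 0.0154%. At 5000 counts a single read passes that bound, so this restates the pattern and does not decide for carry-over of reads between barcoded libraries. Carry-over and real low expression both stay open, because for genes at 500 or more and under 5000 counts the pooled share differed up to 2.70-fold between the libraries of 1 source; that case was nodules, where roots received 0.220% and the other 4 libraries 0.0816% to 0.0976%. Between 3 and 21 detected genes per library had a count of at most 0.1% of the same gene's count in another library, and between 40 and 67 at most 0.25%, which takes in most of the pooled shares (up to 0.253%, leaf to nodules, in sources with 5 or more such genes); at these levels the explanations cannot be told apart.

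Same-structure copies on the 4 haplotypes often shared reads unevenly: among 931 sets of 4 with 100 or more counts in every library, the leading copy took a median of 62.8% of the counts, where an even split gives 25%, and in 254 sets it took 80% or more. The same copy led in all 6 libraries in 100% of those 254 sets, and of 255 sets picked by 80% in roots alone, where the total does not favour that outcome, the copy led in the other 5 libraries in 255. A read assignment or cultivar difference fixed for the copy may account for this. Haplotype differences in expression that hold in every tissue would look alike and were not tested. Where the 2 leading copies both had 600 or more counts (535 sets), the largest difference between their tissue profiles had a median of 0.34 on the log2 scale.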
